A study of Homo sapiens with 18 samples.

How the data were processed

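The table analysed here gives linear signal intensities for 22277 probe sets on 18 arrays, and the intensity values were made by the authors before the files were deposited. The deposited arrays shared a scale, as the 2% trimmed means of 1000.29 to 1000.37 show. The scaling target and the software that summarised the probes are not given in the sources used here. Total RNA was purified on silica columns and biotin-labelled by a cDNA protocol of 1 cycle. Raw probe files were not used here.

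Of the probe sets 62 were array controls, 19064 carried 1 gene symbol, 1043 carried several and 2108 were unnamed. Signals were transformed as log2 of the value plus 32. For each of 11963 genes the probe set with the highest mean was kept, 4310 genes having more than 1. Genes below the 40th percentile of the mean, a signal of 152, were left out, which left 7178. The 1276 probe sets above that level with several symbols or none were tested apart, and 0 passed without a block, while 5 passed for TGFalpha at 120 min and 2 for TGFalpha averaged over the times with the block of replicate number within each time.

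Each gene was fitted in limma (lmFit and eBayes) on the 9 group means with 9 residual degrees of freedom, and p were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons were TGFalpha and insulin against control and against each other at each time, both stimuli against control averaged over the times, the TGFalpha effect at 120 against 30 min, and control at 120 against 30 min. With 2 arrays per group the number of arrays limits the precision. The labels say only that experiments were repeated, so the origin of the replicates is not stated and p measures only the spread between these samples. A fold is 2 to the power of the difference of mean log2 values, so it need not equal the ratio of mean signals. Where an array on the lower side of a difference lay below the filter signal, a bound is given with such arrays raised to that signal, since the fitted log2 value then depends on the added 32.

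Replicate numbers were checked for pairing by correlating, for each of 36 pairs of groups, the deviations of the arrays from their group means across genes. The correlation exceeded 0.1 in 35, the lowest being 0.0943. It had a median of 0.773 for the 9 pairs of groups of the same time and 0.373 for the 27 pairs of different times. The fit chosen before the data were examined has no block, and a fit with the replicate number as a block was chosen beside it. The median residual SD was 0.343 without a block, 0.262 with the replicate number as a block and 0.202 with the replicate number within each time as a block. The fit without a block counts differences shared by arrays of 1 replicate as spread. TGFalpha at 30 and 60 min gave 13 and 67 genes at an unadjusted limma p under 0.05 in that fit. Insulin at those times gave 6 and 29, where chance alone would give 359 in independent tests. Against control only insulin at 120 min exceeded that number, at 394. Counts of 0 and high adjusted p from that fit are therefore not evidence of no change.

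Gene lists were drawn up before the data were examined and tested with camera in limma at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. They were immediate early transcription factors, feedback regulators of ERK and EGF receptor signalling, EGF receptor ligands, extracellular proteases, integrins and matrix adhesion, chemokines and cytokines, NF-kappaB feedback, TGFbeta response, G1 to S, mitotic, ribosome biogenesis, sterol synthesis, FOXO targets, glycolysis, integrated stress response, heat shock, keratinocyte differentiation, basal keratinocyte, wound-associated and epithelial-mesenchymal transition genes, and markers of fibroblasts, melanocytes, endothelial cells and leukocytes. The adjusted p and the counts of list results cover all lists tested, 1 of which is not reported here. "Adjusted over the list alone" means the same limma p adjusted over the members of that list. For each list the medians within replicates 1 and 2 were also taken.

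The naming rule was fixed before the data were examined. For each stimulus against control it takes up to 12 genes that rose most and 8 that fell most among those past the threshold with both treated arrays beyond both control arrays. For each list it takes the 4 members with the largest absolute change. For the other comparisons it takes up to 6 each way, and where under 5 genes passed it takes those and the 3 with the smallest p. Genes named by the rule in 1 comparison may be named in others. Genes that passed only with a block were chosen for naming after their values were seen.

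Other settings fixed before the data were examined were quantile normalization, a pseudocount of 1, no filter, a 60th percentile filter, all probe sets, the replicate number as a block, eBayes with trend and robust settings, only the groups compared, and leaving out each array in turn. Added after the data were seen were a block of replicate number within each time, leaving out the insulin array at 120 min of replicate 1, both together, and, for lists, that block with an estimated correlation.

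The fit was tested on simulated signals for TGFalpha against control at 60 min, with 200 of 7178 genes changed in each of 10 simulations. Without a block it recovered 21.0% of genes changed 2-fold, 81.0% at 4-fold, 95.8% at 8-fold and 98.4% at 16-fold, and 4.33% of calls were false. Noise there was independent between arrays, without the differences between replicates that the real arrays share, so these rates need not hold for the real arrays. With the block of replicate number within each time it recovered 74.8% at 2-fold and 99.0% at 4-fold, and 4.98% of calls were false. That simulation took its noise from the smaller spread of the block fit and added the real differences between replicates and times. The 2 sets of rates are therefore not from the same simulated data. Camera called the changed list in 10 of 10 simulations and a random list in 0 of 10. All 20 members of the changed list were raised and the simulated genes were uncorrelated, so this does not test camera on correlated lists.

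Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.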

Results

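Gene expression was measured on Affymetrix human arrays in primary human keratinocytes, the main cell type of the epidermis, that had been plated on collagen I and kept for 16 h without growth supplements. All plates received 20 ng/ml TGFbeta, which halts the growth of these cells, starting 20 min before the stimulus and staying on to the end. The stimulus was TGFalpha, a ligand of the EGF receptor, insulin at 5 µg/ml, or buffer as the control, and RNA was taken 30, 60 or 120 min later. The 9 groups of treatment and time held 2 arrays each, 18 in all, and the series title places the question in the genes induced by signals for motility. The TGFalpha dose, 20 ng/ml, was given for only some of the arrays.

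The signals of each array had a trimmed mean between 1000.29 and 1000.37, and median signals ran from 202 to 234. After 1 probe set was kept per gene and low signals were left out, 7178 genes were tested with limma. Array signals carry no count depth, so the number of arrays limits the precision. The first 3 principal components held 38.0%, 19.6% and 13.1% of the variance. For 18 of 18 arrays the most similar other array carried the same replicate number, for 15 it had the same time, and for 0 it was the other array of its own group. The insulin array at 120 min of replicate 1 stood apart: its highest correlation with any other array was 0.921, and its 3' over 5' signal ratio for the ACTB control probe sets was 4.71 against at most 1.28 on the other 17.

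**Figure D1:**
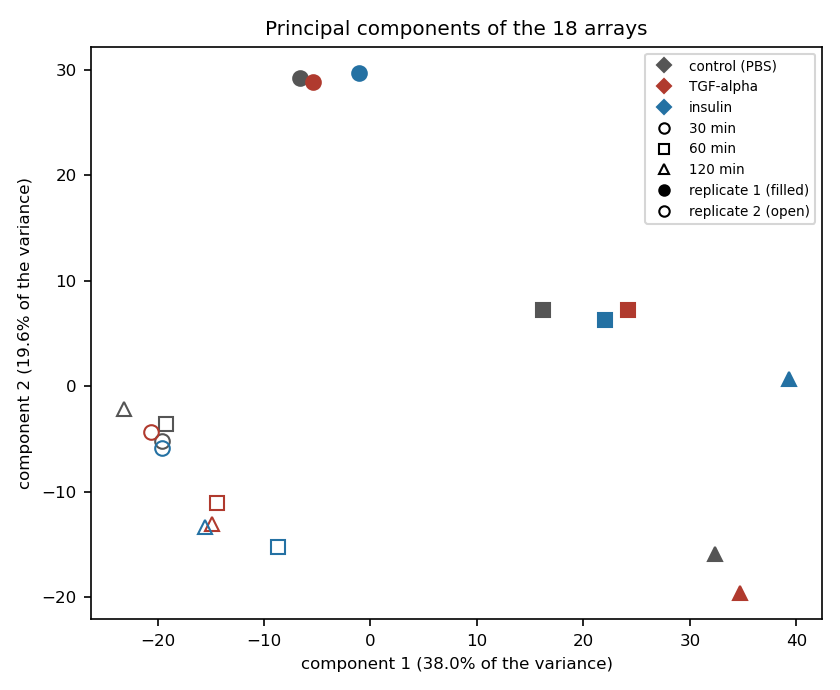
Scores of the 18 arrays on principal components 1 and 2 of the log2 signals, 1 point per array, coloured by treatment with the shape giving the time, filled for replicate 1 and open for replicate 2. Arrays of replicates 1 and 2 lie apart, the replicate 1 arrays spread by time, and the insulin array at 120 min of replicate 1 scores 0.705 on component 2 where the control and TGFalpha arrays of that replicate and time score -15.9 and -19.6.

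At 60 min TGFalpha raised 8 genes and lowered 0 relative to control, in limma at an adjusted p under 0.05 over 7178 genes. They included EGR3 and FOS, immediate early transcription factors of growth factor signalling. EGR3 (probe set 206115_at) went from a signal of 122 ± 66.0 (SD, n = 2) in control to 2825 ± 85.3 with TGFalpha, at least 14.9-fold with control arrays raised to the filter signal of 152, which 1 of them did not reach (fitted log2 4.29, SE 0.68, limma adjusted p = 0.0388). FOS (209189_at) went from 302 ± 3.38 to 6081 ± 235, 18.3-fold (log2 4.19, SE 0.65, limma adjusted p = 0.0388). HBEGF (203821_at), itself a membrane-anchored ligand of the EGF receptor, rose 8.69-fold (SE 0.51 on the log2 scale, limma adjusted p = 0.0433). DUSP6 (208891_at), a phosphatase that inactivates ERK, rose 7.43-fold, and SPRY4 (221489_s_at), another inhibitor of receptor tyrosine kinase signalling with 1 control array below that signal, at least 5.41-fold (limma adjusted p = 0.0258 and 0.0475). The other 3 were PLK3 (204958_at), a polo-like kinase, at 3.55-fold, PTGS2 (204748_at), the inducible cyclooxygenase, at 3.47-fold, and EPHA2 (203499_at), an ephrin receptor, at 3.38-fold (limma adjusted p = 0.0258, 0.0258 and 0.0388). For each of the 8 genes both TGFalpha arrays lay beyond both control arrays, and the changes within replicates 1 and 2 were 4.14 and 4.24 for FOS and 3.20 and 2.59 for DUSP6 (log2).

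With the replicate number as a block in limma the count at 60 min was 14, all higher, and included all 8. The additions were FOSL1, an AP-1 subunit, with a log2 fold change of 2.20 (SE 0.58, limma adjusted p = 0.00102 with the block against 1.0 without it), TRIB1 at 1.92, IER2 at 1.90, DUSP1 at 1.81, VEGFA, the angiogenic growth factor, at 1.71 and PLAUR, the urokinase receptor that focuses plasmin activity at the cell front, at 1.31. A block of replicate number within each time, added after the data were seen, gave 19 genes, and 42 when the insulin array at 120 min of replicate 1 was also left out. LIF, a cytokine of the interleukin 6 family, had a log2 fold change of 2.55 (at least 2.48 by the same bound) and passed only with that added block (limma adjusted p = 0.00346, against 0.818 without a block and 0.0735 with the replicate number as a block). The count of 8 rested on all 4 arrays compared, since it was 0 when any 1 of them was left out, and it was 4 without the apart insulin array of 120 min. At an unadjusted p under 0.05 there were 67 genes without a block and 349 with the added block, where chance alone would give 359 in independent tests.

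**Figure D2:**
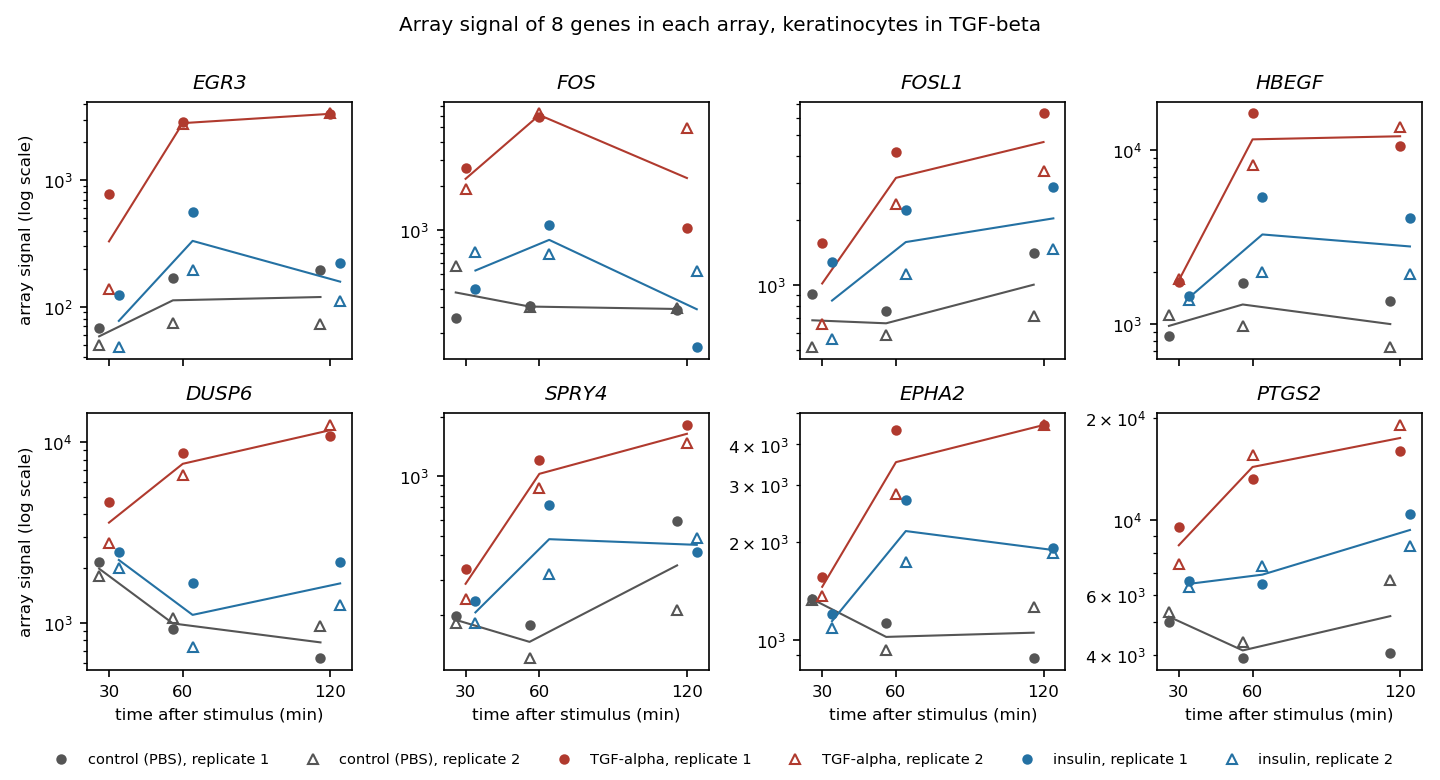
Signal (log axis) against time in min for EGR3, FOS, FOSL1, HBEGF, DUSP6, SPRY4, EPHA2 and PTGS2, with 1 point per array and a line through the geometric mean of both arrays for control, TGFalpha and insulin. With TGFalpha the mean signal of EGR3 was 458, 2825 and 3345 at 30, 60 and 120 min, against 58.9, 122 and 134 in control.

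Among the gene lists fixed before the data were examined, immediate early transcription factors were raised as a group at 60 min of TGFalpha. Of 21 measured members 2 rose over all genes, 8 rose when adjusted over the list alone, and 18 had a value above 0, with a median log2 fold change of 0.56 (camera adjusted p = 5.62e-28, and adjusted p = 0.000194 with an estimated correlation). Negative feedback regulators of ERK and EGF receptor signalling had a median of 1.23 over 12 members, of which 2 rose over all genes and 7 when adjusted over the list alone (adjusted p = 0.000194 with an estimated correlation). Of the 5 EGF receptor ligands 1 rose, HBEGF, also when adjusted over the list alone, and 4 lay above 0 (adjusted p = 0.00858 with an estimated correlation, and 0.0818 when the block of replicate number within each time, a setting added late, was used with it). By fry in limma, a rotation test of whether members move on balance one way, these 3 lists had adjusted p = 0.00396, 0.00396 and 0.0129.

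Chemokines and cytokines lay above 0 at 60 min for 19 of 20 members, with a median of 0.59, 0 members past the threshold over all genes and 2 when adjusted over the list alone. Their camera call was lost with an estimated correlation, at adjusted p = 0.067 with an estimated correlation. IL1A and IL1B, early epidermal alarm cytokines, had log2 fold changes of 1.56 and 1.54 (limma adjusted p = 1.0 for both). NF-kappaB feedback genes (12 of 13 above 0, median 0.36, adjusted p = 0.171 with an estimated correlation), keratinocyte differentiation genes (20 of 21 above 0, median 0.37, 0.459), ribosome biogenesis genes (median 0.17, 0.381), sterol synthesis genes (median 0.13, 0.353) and glucose transport and glycolysis genes (median 0.039, 0.353) also passed only with the preset correlation. FOXO targets, genes that starvation raises, had a median of -0.40 with 3 of 17 above 0 and adjusted p = 0.102 with an estimated correlation. Within replicates 1 and 2 the FOXO median was -0.026 and -0.45, so most of the shift lay in replicate 2. CDKN1B, the cell cycle inhibitor p27, stood at -1.30 (limma adjusted p = 1.0), while TRIB1 in the same list rose when adjusted over the list alone.

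Proteases and adhesion genes, tied to movement through the matrix, had no camera call at 60 min. Extracellular proteases and their inhibitors had 6 of 17 members above 0 (median -0.15 but a mean of 0.050 and a test direction of up, camera adjusted p = 0.876), and integrins and matrix adhesion genes 12 of 18 (median 0.055, 0.557). ITGA5, the fibronectin receptor subunit, had a log2 fold change of 0.84 with an SE of 0.87, and its sign turned when the TGFalpha array at 60 min of replicate 1 was left out, to -0.11.

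By 120 min TGFalpha had raised 5 genes and lowered 0. All 5 were among the 8 of 60 min, where 0.00557 shared genes would be expected if the calls were independent. DUSP6 reached 11672 ± 1148 against 797 ± 227 (SD, n = 2) in control, 14.4-fold (log2 3.84, SE 0.39, limma adjusted p = 0.00248). EGR3 was at least 16.5-fold higher by the bound used at 60 min (fitted log2 4.45, SE 0.68, limma adjusted p = 0.0322) and HBEGF 11.6-fold (log2 3.54, SE 0.51, limma adjusted p = 0.0259), with 2 of its 3 probe sets on the same side. EPHA2 rose 4.25-fold and PTGS2 3.35-fold (limma adjusted p = 0.0179 and 0.0259). FOS had dropped back to 2999 ± 2783 from its level at 60 min, and its log2 fold change over control was 2.84 (limma adjusted p = 0.418), with 1.75 in replicate 1 and 3.93 in replicate 2.

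With the replicate number as a block 14 genes were higher at 120 min and 0 lower, 10 of them shared with the 14 of 60 min. The additions included LIF at a log2 fold change of 2.99 (limma adjusted p = 0.0249 with the block), the ERK phosphatase DUSP5 at 2.19 (0.0182), FOSL1 at 2.17 (0.000583), SPRY4 at 2.10, SPRY2 at 1.79, TRIB1 at 1.99, DUSP1 at 1.92, VEGFA at 1.64 and YRDC, a tRNA modification enzyme, at 1.36. The added block of replicate number within each time gave 41 genes, 37 higher and 4 lower, and 129 (100 higher and 29 lower) without the apart insulin array. That block passed PHLDA1 at 2.78, DUSP4 at 2.69, AKAP12, a kinase scaffold, at 2.12, FOSB at 1.84, the EGF receptor ligands EREG and TGFA at 1.84 and 1.01, IL1B at 1.87, IL24 at 1.83 (at least 0.91, both control arrays being below the filter signal) and the collagenase MMP1 at 1.38 (limma adjusted p = 0.0312). The 4 lower genes, chosen for naming after their values were seen, were OSR2 at -1.61 (-1.56 with arrays raised to the filter signal), the kinetochore gene NDC80 at -1.20 (-1.0), ZNF623 at -0.91 (-0.84) and ZNF552 at -0.86. Without a block the 5 calls became 0 when the control array of replicate 1 or the TGFalpha array of replicate 2 was left out, 1 without the TGFalpha array of replicate 1 and 4 without the control array of replicate 2. There were 137 genes at an unadjusted p under 0.05, and 649 with the added block.

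Gene lists separated further at 120 min of TGFalpha. Feedback regulators had a median log2 fold change of 1.85 over 12 members, with 1 past the threshold over all genes and 7 when adjusted over the list alone (adjusted p = 0.000151 with an estimated correlation). Immediate early factors had a median of 0.88, with 1 up over all genes and 9 up and 1 down when adjusted over the list alone (0.000438 with an estimated correlation). EGF receptor ligands had a median of 1.01, with 1 up over all genes and 3 when adjusted over the list alone (0.00222). Chemokines and cytokines had a median of 1.19, with 18 of 20 above 0, 0 past the threshold over all genes and 5 when adjusted over the list alone (adjusted p = 0.0215 with an estimated correlation). The chemokine median was 0.42 in replicate 1, with 13 above 0, and 1.68 in replicate 2, with 19 above 0.

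At 120 min camera also placed extracellular proteases above the other genes. They had 15 of 17 members above 0 and a median of 0.66, with 0 past the threshold over all genes and 0 when adjusted over the list alone (adjusted p = 0.0215 with an estimated correlation). MMP10, MMP9 and MMP3, metalloproteinases that degrade matrix, had log2 fold changes of 1.80, 1.73 and 1.29 (limma adjusted p = 1.0 for each). By fry in limma the proteases and the chemokines had adjusted p = 0.171 and 0.143. For TGFalpha against insulin their medians were 0.025 and 0.046, with the apart array on the insulin side, and 0.23 and 0.59 in replicate 2. Insulin against control in replicate 2 gave 0.26 and 1.12, so values above 0 there were not particular to TGFalpha. The control array that both comparisons share there was lower than at 30 min, with medians of -0.27 and -0.76. Integrins and matrix adhesion genes had 16 of 18 above 0 and a median of 0.19 (adjusted p = 0.103 with an estimated correlation), with ITGA5 at 1.02 and ITGA2 at 0.75.

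Mitotic genes had 0 of 23 members above 0 at 120 min of TGFalpha, with a median of -0.62, but 0 members passed the test over all genes or adjusted over the list alone and the camera call was lost, at adjusted p = 0.509 with an estimated correlation. Their median was -0.32 in replicate 1 and -0.92 in replicate 2. In replicate 2 insulin against the same control array gave -0.80, and TGFalpha against insulin -0.066, so the low values there were not particular to TGFalpha. That control array was itself higher than control at 30 min, with a median of 0.63 and 23 of 23 members above 0. The values therefore cannot tell a fall with both stimuli from a high control array. Replicate 1 gave 0.36 for insulin, on the apart array. KIF11, a spindle motor, stood at -0.89 and CCNB2, a mitotic cyclin, at -0.84 (limma adjusted p = 1.0 for both), the latter turning to 0.086 without the control array of replicate 2. Calls for genes of the G1 to S transition (median -0.31, adjusted p = 0.583 with an estimated correlation) and for TGFbeta response genes (median 0.14, 0.31) were also lost with the replicate number as a block, at 0.0798 and 0.0613. ID2, which TGFbeta represses, stood at -1.21 (limma adjusted p = 1.0). Calls for NF-kappaB feedback genes (median 0.20, adjusted p = 0.182 with an estimated correlation) and for glycolysis genes (median 0.11, 0.0995, but 0.0379 with the added block as well) were lost too. Medians of the lists without a camera call were -0.006 for the integrated stress response, -0.066 for heat shock genes, -0.14 for keratinocyte differentiation, 0.10 for basal keratinocyte genes, 0.095 for wound-associated genes, 0.19 for epithelial-mesenchymal transition genes, 0.047 for ribosome biogenesis, -0.017 for sterol synthesis and -0.16 for FOXO targets. The test direction was up for the stress response and sterol lists, against the sign of their medians. At 60 min the medians of the lists not yet named were -0.071 for TGFbeta response, -0.025 for G1 to S, -0.15 for mitotic, 0.067 for integrated stress response, 0.078 for heat shock, 0.034 for basal keratinocyte, 0.085 for wound-associated and 0.021 for epithelial-mesenchymal transition genes, with no camera call.

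**Figure D3:**
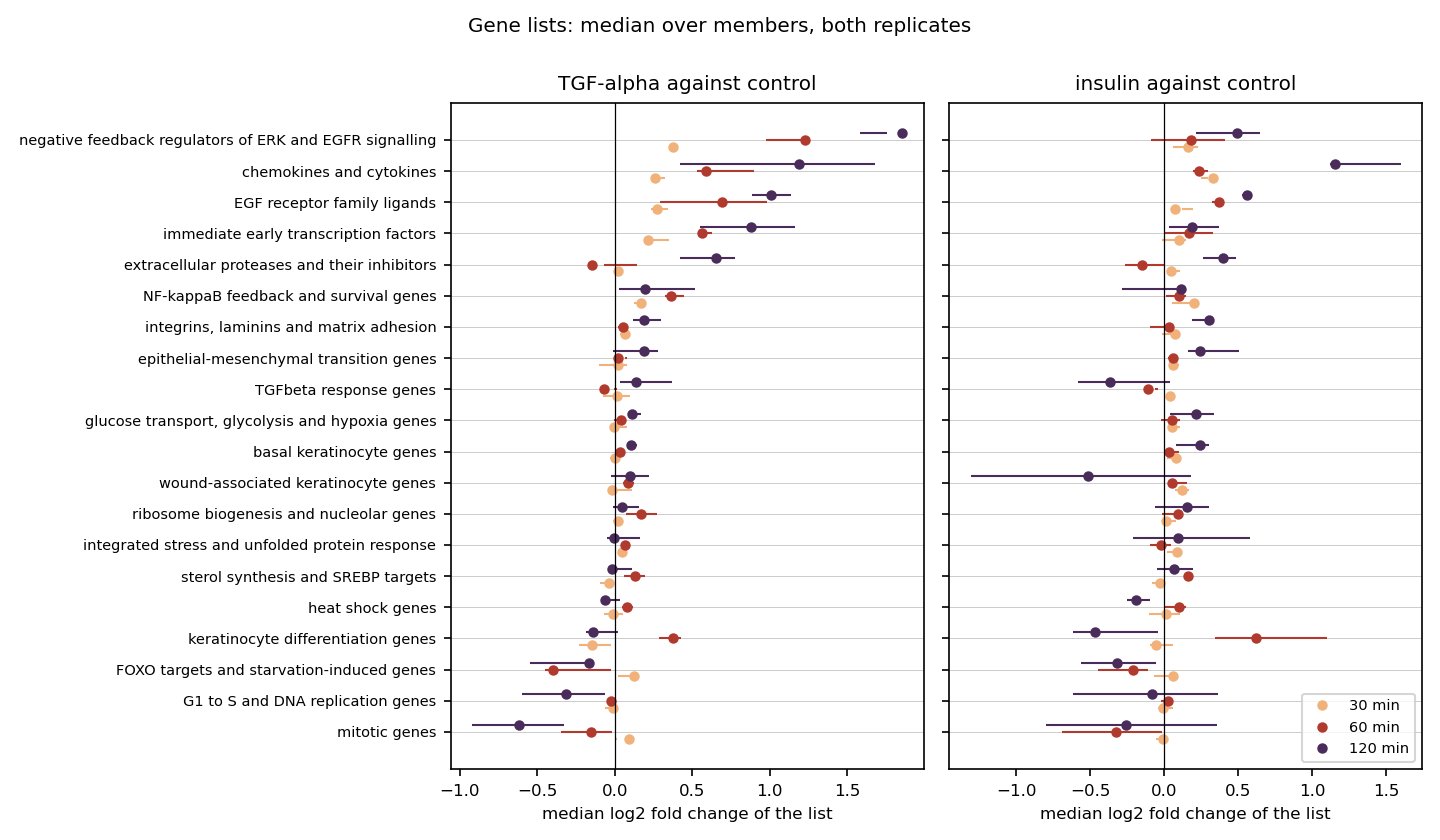
Median log2 fold change over the measured members of each gene list in the comparisons with control at each time, with a dot at the median of the fitted values and a line spanning the medians of replicates 1 and 2, outside which the dot may fall. Feedback regulators stand at 1.23 and 1.85 with TGFalpha at 60 and 120 min, and mitotic genes at -0.62 at 120 min, the lowest of its panel.

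At 30 min of TGFalpha no single gene passed, and immediate early and feedback genes lay above the other genes as lists in a call that an estimated correlation kept without a block but not with the added block within each time. FOS had a log2 fold change of 2.47 (SE 0.65), EGR3 of at least 1.01 with its control arrays, both below the filter signal, raised to that signal (fitted 2.04, SE 0.68), EGR1, a zinc finger factor of the same early wave, of 1.56 and IER2 of 1.36, each with a limma adjusted p of 1.0. FOS stood at 3.24 in replicate 1 and 1.69 in replicate 2. Of the 21 members of that list 16 lay above 0 with a median of 0.22, 0 passed over all genes and 1 rose when adjusted over the list alone (adjusted p = 0.00813 with an estimated correlation). The feedback list had 10 of 12 above 0 and a median of 0.37, with 0 past the threshold over all genes and 0 when adjusted over the list alone (adjusted p = 0.00813 with an estimated correlation). DUSP1 stood at 1.25, DUSP6 at 0.84 and HBEGF at 0.85. Chemokines, with CXCL2 at 1.13, had a median of 0.26 and lost their call at adjusted p = 0.508 with an estimated correlation. HHAT, a palmitoyltransferase for Hedgehog proteins and the gene with the smallest p, stood at -0.88 (-0.49 with arrays raised to the filter signal). Limma gave 0 genes without a block, with the replicate number as a block and with either added block, and 13 at an unadjusted p under 0.05. By fry in limma the 2 lists had adjusted p = 0.734 and 0.773, and both calls were lost at adjusted p = 0.174 with an estimated correlation and the added block. Fibroblast markers had a median of 0.34 at 30 min, above that of the immediate early list, with 8 of 9 members above 0 and 0.24 and 0.28 in the 2 replicates (camera adjusted p = 0.205, 0.00347 with the added block, and 0.352 with the added block and an estimated correlation).

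Averaged over the 3 times, 6 TGFalpha arrays against 6 controls, 10 genes rose and 0 fell. They were the 8 genes of 60 min with DUSP1, an ERK and p38 phosphatase (log2 1.66, SE 0.26, limma adjusted p = 0.0199), and YRDC (0.93, SE 0.14, limma adjusted p = 0.0136). The mean fitted log2 fold changes of EGR3, FOS, DUSP6 and HBEGF were 3.59 (at least 2.98 by the bound), 3.17, 2.52 and 2.50 (limma adjusted p = 0.00163, 0.00224, 0.00058 and 0.00224). The count was 24 with the replicate number as a block, 47 (44 higher and 3 lower) with the added block within each time, 117 with that block and without the apart array, and 15 without a block and without the apart array. The 3 lower genes were ID2 at -1.07, CDKN1B at -0.84 and BCL6 at -0.64, chosen for naming after their values were seen. Without a block the count was 6 without the TGFalpha array at 30 min of replicate 1 or the control array at 60 min of replicate 2. Immediate early factors, feedback regulators and EGF receptor ligands were above the other genes (adjusted p = 6.37e-05, 5.8e-05 and 0.00137 with an estimated correlation), with 2, 3 and 1 members up over all genes and 12, 7 and 2 when adjusted over the list alone. Chemokines and cytokines, with a median of 0.68, 0 members past the threshold over all genes and 4 when adjusted over the list alone, had adjusted p = 0.0118 with an estimated correlation. Calls with the preset correlation were lost for proteases (0.124), integrins (0.147), NF-kappaB feedback genes (0.0897), mitotic genes (0.553), ribosome biogenesis genes (0.452) and glycolysis genes (0.106), at the adjusted p in parentheses with an estimated correlation. With the added block as well the proteases and the glycolysis genes passed, each at adjusted p = 0.0436 with an estimated correlation.

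Whether the TGFalpha effect differed between 30 and 120 min was tested directly. DUSP6 had a difference of 3.01 (log2, SE 0.56), HBEGF of 2.69 (SE 0.72) and EPHA2 of 1.96 (SE 0.39), with limma adjusted p = 0.892, 1.0 and 0.892. Feedback regulators changed more at 120 min as a group (median difference 0.97, adjusted p = 0.000996 with an estimated correlation), as did EGF receptor ligands (1.04, 0.0127) and immediate early factors (0.43, 0.0127). With the added block as well the feedback list held at 0.0367, while the ligands and immediate early factors were lost at adjusted p = 0.0998 and 0.137 with an estimated correlation. Proteases and chemokines lost their calls, at adjusted p = 0.0519 and 0.118 with an estimated correlation (0.0367 and 0.0873 with the added block as well), as did integrins (0.291), NF-kappaB feedback genes (0.434), glycolysis genes (0.23) and mitotic genes (median -0.65, 0.522). Over all genes 0 members of any list passed, and 2 feedback regulators and 1 EGF receptor ligand passed when adjusted over the list alone. The median difference of immediate early factors was -0.033 in replicate 1 and 0.87 in replicate 2. Limma gave 0 single genes without a block and with either block, 45 at an unadjusted p under 0.05, and 12 with the added block and without the apart array.

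Insulin at 60 min gave 0 genes past the threshold in limma. The largest positive values belonged partly to genes that TGFalpha raised and partly to genes of keratinocyte differentiation. SPRY4 had a log2 fold change of at least 1.40 (fitted 1.53, SE 0.43), EGR3 of at least 0.94 (fitted 1.33) and LIF of at least 1.08 (fitted 1.14), each with 1 control array below the filter signal. FOS stood at 1.42, HBEGF at 1.32, FOSL1 at 1.22 and EPHA2 at 1.06, and all 7 had a limma adjusted p of 1.0. ARTN, a ligand of the RET receptor complex and the gene with the smallest p, stood at 1.01 (SE 0.25) and CCNG2, a cyclin that FOXO factors induce, at -1.30. Limma gave 29 genes at an unadjusted p under 0.05, 0 with the replicate number as a block, 0 with the added block within each time and 5 when that block was used without the apart array. Camera with the preset correlation placed immediate early factors, feedback regulators, EGF receptor ligands and chemokines above the other genes, and FOXO targets, proteases and mitotic genes below. None of these held with an estimated correlation, where the adjusted p were 0.249, 0.329, 0.249, 0.568, 0.216, 0.568 and 0.735. Feedback regulators had 1 member up when adjusted over the list alone and the other 6 had 0. In replicates 1 and 2 the medians were 0.33 and 0.00086 for immediate early factors and 0.41 and -0.091 for feedback regulators. They were -0.015 and -0.69 for mitotic genes and 0.0027 and -0.26 for proteases, so the shifts of these lists lay mostly in 1 replicate. EGF receptor ligands (0.32 and 0.40), chemokines (0.30 and 0.20) and FOXO targets (-0.11 and -0.45) kept their sign in both.

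Keratinocyte differentiation genes lay above 0 for 21 of 21 members at 60 min of insulin, with a median of 0.62, 0 members past the threshold over all genes or adjusted over the list alone, and adjusted p = 0.528 with an estimated correlation. The median was 0.34 in replicate 1 and 1.10 in replicate 2. IVL, a precursor of the cornified envelope, stood at 2.22 with an SE of 1.62. The insulin arrays at 30 min showed 0 genes (6 at an unadjusted p under 0.05, 0 with either block or without the apart array), and the smallest p belonged to the kinesin KIFC3 at 1.35 (at least 0.58 by the bound), the interferon receptor subunit IFNAR1 at -0.65 and the fucosyltransferase FUT1 at 0.63 (0.62). Chemokines were the only list with a camera call at 30 min (median 0.33, 16 of 20 above 0), and it was lost at adjusted p = 0.931 with an estimated correlation.

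At 120 min of insulin 0 genes passed in limma, with 394 at an unadjusted p under 0.05 and 0 with either block or without the apart array. One of the 2 insulin arrays of this time is the array that stood apart, with an ACTB 3' over 5' ratio of 4.71 against at most 1.28 on the other 17. Across genes, the insulin minus control differences of replicates 1 and 2 correlated at 0.00659 (Pearson, genes not being independent replicates). CXCL8, the neutrophil chemokine interleukin 8, stood at 2.40 (3.25 in replicate 1 and 1.56 in replicate 2) and CXCL5 at 2.26 (limma adjusted p = 0.847 for both). EREG stood at 1.58, PHLDA1 at 1.55, HBEGF at 1.45, MMP1 at 1.83 and CDKN1B at -1.13. The smallest p belonged to RANBP3 at -1.61, AGR2 at -2.03 and AAAS at -1.84, or -1.19 for RANBP3 and -0.99 for AAAS with arrays raised to the filter signal (limma adjusted p = 0.847 for each), and only 1 of the 4 probe sets of RANBP3 lay on that side. When the replicate 2 array was left out, so that the apart array stood alone, the count was 392.

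Chemokines and cytokines had a median of 1.15 at 120 min of insulin, with the apart array among the 2, 0 members past the threshold over all genes, 4 when adjusted over the list alone and adjusted p = 0.255 with an estimated correlation. Calls for feedback regulators (median 0.49), EGF receptor ligands (0.56) and FOXO targets (-0.32) were lost at adjusted p = 0.255 with an estimated correlation, and that for proteases (0.40) at 0.352, each list with 0 members up or down when adjusted over the list alone. Averaged over the times, insulin against control gave 0 genes in limma, 88 at an unadjusted p under 0.05, 0 with either block and 1 with the added block and without the apart array. YRDC stood at 0.69, FUT1 at 0.67 (at least 0.65) and PTGS2 at 0.63 (limma adjusted p = 1.0 for each). The lowest list p were those of feedback regulators, EGF receptor ligands, chemokines and FOXO targets, each at adjusted p = 0.0698 with an estimated correlation, with medians of 0.34, 0.36, 0.63 and -0.19 and only 1 member, an EGF receptor ligand, up when adjusted over the list alone. Mitotic, immediate early, glycolysis and ribosome biogenesis genes also lost their calls, at 0.606, 0.251, 0.316 and 0.559.

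TGFalpha and insulin were compared directly, which leaves the control arrays out of the contrast. At 60 min DUSP6 was 2.74 (log2, SE 0.39) higher with TGFalpha (limma adjusted p = 0.0917, and 0.0346 with the replicate number as a block), EGR3 2.96 (1.0 and 0.0762), FOS 2.78 and TRIB1 1.56. At 120 min EGR3 was at least 3.96 higher (fitted 4.14, limma adjusted p = 0.162, and 0.00507 with the block), DUSP6 2.79 (0.0754 and 0.0142), TRIB1 1.97 (0.909 and 0.0169) and DUSP1 1.51 (0.909 and 0.0305). JUNB, an AP-1 subunit, at 1.87, HBEGF at 2.09, EPHA2 at 1.26 and FOSL1 at 1.17 passed only with the added block within each time. At 30 min FOS stood at 2.01, EGR3 at 1.73 (at least 1.01 by the bound) and HHAT at -0.73 (-0.35). The counts without a block were 0, 0 and 0 at 30, 60 and 120 min, with 6, 32 and 363 genes at an unadjusted p under 0.05. They were 0, 1 and 4 with the replicate number as a block, 0, 2 and 8 with the added block, and 0, 3 and 8 with that block and without the apart array.

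As groups, immediate early factors and feedback regulators were higher with TGFalpha than with insulin at 60 min, with an estimated correlation and with or without the added block. Their calls at 120 min, and that of immediate early factors at 30 min, held with an estimated correlation only without that block. Immediate early factors had, at 30, 60 and 120 min, medians of 0.26, 0.55 and 0.57 (adjusted p = 0.0147, 0.000221 and 0.0132 with an estimated correlation). With the added block as well these were 0.443, 0.0347 and 0.294, so the calls at 30 and 120 min were lost. Over all genes 0 members passed at each time, and 0, 3 and 5 passed when adjusted over the list alone. Feedback regulators had medians of 0.93 at 60 min and 1.21 at 120 min (0.000128 and 0.00645, and 0.00936 and 0.099 with the added block as well), with 1 and 6 members up when adjusted over the list alone, and a median of 0.30 at 30 min, where the call was lost at adjusted p = 0.0832 with an estimated correlation. EGF receptor ligands had a median of 0.32 at 60 min (adjusted p = 0.0311 with an estimated correlation, lost at 0.122 with the added block as well). At 60 min preset calls for chemokines (0.214), NF-kappaB feedback genes (0.242), proteases (0.255), the integrated stress response (0.32) and mitotic genes (0.741) were lost at the adjusted p in parentheses with an estimated correlation. At 120 min TGFbeta response genes had a median of 0.52 and lost their call at adjusted p = 0.35 with an estimated correlation, with the apart insulin array on the other side of that contrast.

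Across genes the changes with TGFalpha and with insulin correlated at 0.59, 0.671 and 0.375 at 30, 60 and 120 min. Both use the same control arrays, and simulated unchanged groups compared with shared controls gave 0.497, 0.50 and 0.502. The covariances, 0.0184, 0.0445 and 0.0521, lay below the 0.0869, 0.0875 and 0.0878 simulated without a block, and at 60 and 120 min above the 0.0267 and 0.0268 simulated with the added block within each time. No gene was called for both stimuli, since insulin had 0 calls.

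Control arrays at 120 min were compared with those at 30 min, and most of the larger differences lay in replicate 1. MYC, the growth-promoting factor that TGFbeta represses, went from 4606 ± 279 to 1418 ± 155 (SD, n = 2), a log2 change of -1.68 with -1.85 and -1.51 in the 2 replicates (limma adjusted p = 0.999). NRIP3 stood at -1.43 (-1.10 with arrays raised to the filter signal) and INAVA at 2.17 with the same adjusted p. IVL stood at 3.21, with 6.43 in replicate 1 and -0.01 in replicate 2, and at least 3.15 by the bound. TGM1, the enzyme that crosslinks the cornified envelope, stood at least at 1.77 and the desmosomal cadherin DSC1 at least at 1.04 (fitted 3.05 and 2.21), all their control arrays at 30 min being below the filter signal. Differentiation genes had 21 of 21 members above 0 and a median of 1.37 (1.98 in replicate 1, 0.18 in replicate 2), and mitotic genes 0 of 23 and a median of -0.65 (-1.97 and 0.63). With 0 members of either list past the threshold over all genes or adjusted over the list alone, both calls were lost at adjusted p = 0.407 and 0.759 with an estimated correlation, as were those of G1 to S genes (0.759) and wound-associated genes (0.407). When adjusted over the list alone 1 epithelial-mesenchymal transition gene rose, and 1 immediate early factor and 2 feedback regulators fell. Limma gave 0 genes without a block and with the replicate number as a block, and 232 at an unadjusted p under 0.05. At least 2-fold changes numbered 1020 in replicate 1 and 136 in replicate 2, and the changes correlated across genes at -0.139 between them.

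Markers of other cell types were looked up to see what else the cultures could hold. Of 8 endothelial markers 0 passed the filter, the highest mean signal being 85.7, and of 11 leukocyte and Langerhans cell markers 0 passed, the highest being 110. Among 8 melanocyte markers MITF alone passed, at a mean signal of 280. Of 14 fibroblast markers 9 passed, led by TAGLN at 6978, an actin-binding protein that TGFbeta also induces in epithelial cells. FBN1 at 967, COL5A2 at 849 and COL1A1 at 620 were among the others. COL1A2, COL3A1, COL6A3, PDGFRA and PDGFRB did not pass. Whether the cultures held some fibroblasts stays open. Without a block the fibroblast list had no camera call in any of the comparisons, with medians of 0.34, -0.13 and -0.019 at 30, 60 and 120 min of TGFalpha. With the added block it had calls at 30 min and averaged over the times (camera adjusted p = 0.00347 and 0.0496), both lost with an estimated correlation (0.352 and 0.402).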

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

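The regrouping tests below were written before their values were seen, and the other tests were chosen after the result was seen. Among control probe sets, which were not part of any comparison, the 3' over 5' ratio of ACTB was 4.71 on the insulin array at 120 min of replicate 1 against at most 1.28 on the control arrays.

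The insulin array at 120 min of replicate 1 stood apart from the other 17. The 1% of genes with the highest signals were higher than on the replicate 1 arrays of that time by a median of 0.92 (log2), against 0.011 over all genes. A signal ceiling that this array lacks would give that. The differences also spread widely at low signals. Their median absolute deviation, scaled as an SD, was 0.73 in the lowest 25% of genes and 0.67 over all genes. A ceiling on the highest signals could not account for that spread. A response to 120 min of insulin wide enough to set the array apart would have appeared in both replicates, yet the changes correlated across genes at 0.00659. A response of fewer genes is not excluded, since TGFalpha against control at 120 min gave only 0.357 between replicates. Insulin changes of at least 2-fold in both replicates went the same way for 23 genes and opposite ways for 22. The GAPDH 3' over 5' ratio of 0.986 lay within the 0.892 to 1.03 of the other arrays, and the ACTB ratio came from a 3' signal of 163114 with a 5' signal of 34630 inside the range of the others. These values do not settle the quality of the RNA, and whether RNA quality, scanning or both set this array apart stays open.

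Arrays of 1 replicate number and time resembled each other more than arrays of 1 treatment. Time on the plate in TGFbeta, alike in both replicates, is argued against as the main source. The control changes from 30 to 120 min correlated across genes at -0.139 between the replicates. A shared effect of time in fewer genes is not excluded. Control changes of at least 2-fold in both replicates went the same way for 27 genes and opposite ways for 33. The SD over genes of the control change from 30 to 120 min was 2.08 times as large in replicate 1. This may point to a difference between the time sets of replicate 1 alone, such as separate plates, lots of cells or array batches. The labels do not tell these apart. With the replicate number within each time as a block TGFalpha against control at 120 min gave 41 genes in place of 5.

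Genes raised by TGFalpha were also higher with insulin at 60 min. Shared control arrays could make such a pattern, so 50 genes were picked on TGFalpha in 1 replicate and insulin was measured in the other. The 2 medians were 0.60 and 0.67 (log2), with 48 and 41 of 50 genes above 0. Both lay at the 100th percentile of 10000 random sets matched on level. This argues against control arrays shared by picking and measuring as the only source. The random genes were drawn singly, so the percentile does not allow for early genes that move together on 1 control array. In replicate 2 the insulin medians of the immediate early and feedback lists were 0.00086 and -0.091, against 0.33 and 0.41 in replicate 1. No single gene passed for insulin at 60 min, and a common effect of handling or of adding fluid other than the buffer was not tested. Whether insulin itself raises part of the same genes therefore stays open.

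Regrouping the control and treated arrays within each time gave at least as many genes as the real grouping for TGFalpha averaged over the times, 10, in 9 of 100 splits, the real one included, and up to 1650 genes in another. By this planned test that count alone may reflect grouping by chance. Every other split with as many genes, however, left some of the 6 pairs of the same replicate and time together. Such splits compare replicates in part, and the one with 1650 genes parted 0 of these pairs. The planned test therefore cannot tell chance from differences between replicates. In the 30 splits that part all 6 pairs only the real one reached 10, the next giving 7. For insulin the real count was 0, which any split reaches, so the 100 of 100 splits that did, with a highest other count of 0, do not test it.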

How the results depend on the processing

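Alternatives with the replicate number within each time as a block, and those without the insulin array at 120 min of replicate 1, were chosen after the result was seen, and the others were planned. For TGFalpha against control at 60 min the count of 8 became 4 with quantile normalization, 5 with a pseudocount of 1, 2 without the filter, 14 with the replicate number as a block, 1 with only the groups compared, 19 with the block within each time, 4 without the apart array and 42 with both. For TGFalpha at 120 min the 5 became 2 without the filter, 14 with the replicate number as a block, 0 with only the groups compared, 41 with the block within each time, 8 without the apart array and 129 with both. For TGFalpha averaged over the times the 10 became 24, 47 and 117 with the replicate number as a block, the block within each time and both changes. TGFalpha against insulin at 60 min went from 0 to 1 with all probe sets, 1 with the replicate number as a block, 2 with the block within each time and 3 with both. At 120 min it went from 0 to 1 with a 60th percentile filter, 2 with all probe sets, 4 with the replicate number as a block, 8 with the block within each time, all higher with TGFalpha, and 8 with both, 7 higher and 1 lower. With both changes insulin at 60 min gave 5 genes, insulin averaged over the times 1 and the TGFalpha effect at 120 against 30 min 12. Leaving out 1 array gave 0 at 60 min of TGFalpha whichever it was. At 120 min it gave 0 without control replicate 1 or TGFalpha replicate 2, 1 without TGFalpha replicate 1 and 4 without control replicate 2. TGFalpha averaged over the times ranged from 6, without TGFalpha at 30 min replicate 1 or control at 60 min replicate 2, to 11 without control at 120 min replicate 2 or TGFalpha at 30 min replicate 2. TGFalpha against insulin at 60 min ranged from 0 to 1, the latter without insulin replicate 1. Without insulin at 120 min replicate 2 the counts were 392 for insulin at 120 min, 352 for TGFalpha against insulin at 120 min and 15 for insulin averaged over the times, against lowest values of 0 each. There the apart array stood alone, and a lone array is assumed to vary like the other groups. ITGA5 at 60 min of TGFalpha ranged from -0.11 without TGFalpha replicate 1 to 1.79 without TGFalpha replicate 2, and CCNB2 at 120 min from -1.77 without control replicate 1 to 0.086 without control replicate 2. Of the results for named genes the replicate number as a block added 20 calls and ended 0, leaving out the filter ended 9, and fitting only the groups compared ended 13. Over 8 comparisons, those of TGFalpha with insulin and the averages over the times not being counted, the estimated correlation ended 38 list calls, and the replicate number as a block added 4 and ended 8. The cause was not tested for any changed result. Signals near background compress small changes, so genes below the filter could not be called here.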

Other observations

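Of the tests drawn on here, those with the block within each time and those without the apart array were chosen after the result was seen, while the comparisons, the gene lists, the estimated correlation and the replicate number as a block were planned. TGFalpha raised genes of 2 opposing kinds in these cells. HBEGF is a ligand that feeds the EGF receptor, as are EREG and TGFA, which passed at 120 min only with the added block within each time. DUSP6, DUSP1 and SPRY4 damp the ERK pathway below the receptor. As a group the feedback regulators changed more by 120 min than by 30 min, with a median difference of 0.97 (log2). The difference for immediate early factors was -0.033 in replicate 1 and 0.87 in replicate 2. Their medians at 30, 60 and 120 min of TGFalpha were 0.35, 0.63 and 0.55 in replicate 1 and 0.21, 0.59 and 1.16 in replicate 2. No test compared 120 with 60 min, so whether the first wave had passed its peak by 120 min stays open.

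For motility the picture is narrower. EPHA2 rose at 60 and 120 min and PLAUR passed at 60 min with the replicate number as a block, where 14 genes were called. Proteases had a camera call at 120 min with 0 members past the threshold over all genes, the direct test of 120 against 30 min gave adjusted p = 0.0519 in limma's camera with an estimated correlation and 0.0367 with the added block as well, and integrins did not hold with an estimated correlation. The protease median for TGFalpha against insulin at 120 min was 0.025, the apart array included, and 0.23 in replicate 2. Whether protease and adhesion genes change later than the early factors stays open. In data simulated without the differences between replicates that the real arrays share, 8-fold changes were recovered more often than 2-fold ones, 95.8% against 21%. Small changes may have been missed.

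Without a block 0 genes differed between TGFalpha and insulin at any time, and DUSP6 at 60 min had a limma adjusted p of 0.0917. DUSP6 was higher with TGFalpha than with insulin at 60 min with the replicate number as a block, the 1 gene called there, and EGR3, DUSP6, TRIB1 and DUSP1 were the 4 at 120 min, with 0 genes higher with insulin. The list calls for immediate early factors and feedback regulators at 120 min were lost with an estimated correlation and the block within each time, at adjusted p = 0.294 and 0.099 in limma's camera. The apart array bears on the insulin side at 120 min, where the block within each time gave 8 genes higher and 0 lower with TGFalpha, and 7 and 1 without that array. FOXO targets, which insulin signalling is known to lower, had a median of -0.19 with insulin averaged over the times, the apart array included. With an adjusted p of 0.0698 in limma's camera at an estimated correlation the list gave no call. Its median with TGFalpha averaged over the times was -0.15. Both averages use the same control arrays, which can give a like sign, so these medians do not tell whether a lowering is particular to insulin. Any lowering remains a candidate for more arrays.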
